A study of Glycine max with 12 samples.

How the data were processed

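The study profiled 3 tissues of waterlogged soybean hypocotyl on 12 Agilent arrays with 2 colours, design 016772. Each array held cortex RNA in 1 dye and RNA of phellogen or of aerenchymatous phellem (AP) in the other. There were 6 arrays of phellogen against cortex and 6 of AP against cortex. In each set the tissue was labelled with Cy3 on 3 arrays and with Cy5 on 3, so a dye effect cancels in the mean of a set. Per the labels, tissues were isolated by laser microdissection, RNA was extracted from each and 10 ng was labelled for each channel. The labels call the 6 replicates of each set biological. They do not say which plants each capture came from, and p-values therefore rest on arrays.

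Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1, protocol GE2_105_Dec08. The intensity values deposited by the authors are the mean brightness of each spot and the median brightness of its local background in both dyes, not normalized, together with processed intensities that the scanner software had detrended and dye-normalized. The log10 values deposited by the authors are the scanner software's ratio of Cy5 over Cy3 after that processing. The other values deposited by the authors are flags of the scanner software for control spots, spots well above background, saturated spots and uneven spots. The series' own value table held the same log10 ratios as the scanner files, with a largest difference of 5e-10 and a median of 0 on each array, so its scale, centring and direction were known.

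Background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The offset draws small signals together, so folds are understated for dim probes. Control spots (1417 per array) were left out, and spots with an outlier flag had weight 0, 16 of them among the probes later tested. No spot was saturated. Of 42748 probes, 15981 were well above background on at least 50% of the arrays of at least 1 tissue and were tested. The other 26767 were left out as dim. The 12 arrays were fitted together in limma with a coefficient for phellogen, a coefficient for AP and a dye term, which left 9 residual degrees of freedom (prior 4.92, median residual SD 0.148). A probe was called at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all probes tested. The dye term itself passed this threshold for 2710 probes. AP was compared with phellogen by the difference of the 2 coefficients, which runs through the cortex channel and assumes that the cortex RNA of both sets of arrays is alike.

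Genes are named as the array's probe descriptions name them. None of the 42748 probe identifiers matched the 59048 genes of the reference table, so no coordinates are given. Different probes of 1 gene were kept apart, and each expressed sequence tag counted as its own gene in the gene lists. The 15981 probes carried 10697 distinct descriptions. For naming, the brightest probe was taken among those with the same description. The naming rule took, for each comparison with cortex, the 10 largest rises and 10 largest falls among called probes with an informative description and the same sign on all 6 arrays. For AP against phellogen it took 6 each way, with all 6 ratios of one tissue beyond all 6 of the other. For each gene list it added up to 2 called members each way. It took 130, 124 and 123 genes for phellogen against cortex, AP against cortex and AP against phellogen. For length, 77 probes are described, picked from these with their values in view.

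Gene lists were word patterns on the descriptions: 28 fixed lists, of which 24 had at least 5 measured probes and were tested, and 8 added after the descriptions had been read but before any ratio was looked at, of which 6 were tested. Lists were tested with camera in limma on the same fit, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. The 24 fixed and the 6 added lists were adjusted apart. The test was repeated with a correlation estimated for each list. With the estimated correlation, 0 of the shifts of the fixed lists passed the threshold in any comparison, so each shifted list's p with the estimated correlation is printed beside it. With 1 probe per description, 6, 5 and 8 fixed lists were shifted, against 9, 7 and 11 with every probe.

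The model, the threshold, the 28 lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives were other normalizations, background corrections and filters, the scanner's own ratios, the deposited value table, fits without the dye term, with the replicate number or the slide as a block, with array weights, a stricter threshold of 0.01, and each array left out in turn. Added after the files had been seen were the slide as a fixed block, slide 2 alone, a pair of further splits of the arrays, the 8 lists and 1 probe per description. In all, 31 settings of the probe fit were run. Arrays lay on 3 slides, each scanned once: phellogen replicates 1 to 4 on slide 1, phellogen replicates 5 and 6 with AP replicates 1 and 2 on slide 2, and AP replicates 3 to 6 on slide 3. Figures were drawn with matplotlib 3.10.9.

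The fit and the list test were tried on simulated log2 ratios in which 200 of 15981 probes were changed by known folds. Background correction, loess and the filter were not part of the simulation. The share changed was also far smaller than the 70.4%, 33.7% and 55.3% of probes called in the data. For phellogen against cortex, 95.5% of probes changed by 1.5-fold were called in the right direction, and 100% of those changed by 2-fold. For AP against cortex these shares were 92.5% and 98.5%. For AP against phellogen they were 82.1% and 100% with the change placed in phellogen, and 79.1% and 98.5% with it placed in AP. Between 8 and 15 unchanged probes were called in these simulations. A shifted list was recovered and 0 of 50 unchanged lists were called. Those lists were random probes with independent noise, so the result does not cover lists whose genes vary together. For arrays, signal over background takes the place of depth, and the number of arrays limits the precision.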

Results

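Soybean (Glycine max, cultivar Enrei) seedlings about 10 days old were waterlogged for 5 days, with the water kept 3 cm above the soil. Under such flooding the hypocotyl forms a spongy secondary tissue, the aerenchymatous phellem (AP), from a lateral meristem, the phellogen. RNA of laser-captured phellogen, AP and cortex was hybridised to 12 arrays with 2 colours, 6 of phellogen against cortex and 6 of AP against cortex, with dyes swapped evenly. The share of probes well above background was 30.6% to 37.3% in the phellogen channels, 17.7% to 31.4% in the AP channels and 25.6% to 34.8% in the cortex channels. For AP it was 17.7% to 23.7% with AP in Cy3 and 27.8% to 31.4% with AP in Cy5. Among 15981 probes tested, array ratios correlated at 0.849 to 0.947 between phellogen arrays and at 0.533 to 0.888 between AP arrays (across probes, which are not independent replicates). Ratios below are log2 of tissue over cortex with the SE of the limma fit (6 arrays per tissue), and adjusted p-values are from limma. That fit pools the spread of all 12 arrays, so a probe's SE is about the same for both tissues. It can understate the spread in the more variable tissue. For isoflavone synthase IFS1 the SD over arrays was 0.196 in phellogen and 0.790 in AP. Where list counts with another normalization, median centring, are given, the adjusted p printed after them is that of the main fit unless stated otherwise.

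The first comparison asked which transcripts set the phellogen apart from the cortex. Phellogen had higher transcript levels of core histones, cell cycle genes and ribosomal proteins, and lower levels of photosynthesis, phenylpropanoid and isoflavonoid genes. With an estimated correlation, none of these list shifts passed the test. The largest rises were in a proline-rich cell wall protein, PvPRP1 (CO982541.1_593, 4.43 ± 0.20, 21.6-fold, well above background on 7 of 12 cortex channels), a lipid transfer-like protein (AW100855.1_414, 4.30 ± 0.16) and histone H3. The largest falls were in a hydroxyproline-rich protein (GMFL01-36-B06-R_387, -5.71 ± 0.18, 52.2-fold lower) and in asparagine synthetases, which make asparagine from aspartate. Of the 15981 probes, 11251 passed the test (70.4%), 5785 higher and 5466 lower in phellogen, and 8854 of them had the same sign on all 6 arrays. Among the 11251 called, 885 were higher and 850 lower by at least 2-fold, 1735 in all, against 2789 with a background offset of 16 and 6238 on the scanner's log ratio.

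Core histones package newly replicated DNA, and the list named for them also admits the linker histone H1. They were higher in phellogen for 30 of 36 measured probes, lower for 3 and not past the test for 3. Adjusted over the list alone, they had the same counts. Their mean ratio was 1.61 (adjusted p = 4.37e-11; adjusted p = 0.182 with an estimated correlation). Probes for histone H3 rose most, GMFL01-25-K12-R_336 by 4.03 ± 0.16, CX706384.1_491 by 4.01 ± 0.15 and BE821002.1_520 by 3.94 ± 0.11, and a probe described as histones H3 and H4 (GMFL01-39-H21-R_308) by 3.38 ± 0.11. In cortex these 4 probes were well above background on 6 to 8 of 12 arrays. Cell cycle and replication genes were higher for 38 of 50 probes, lower for 2 and not past the test for 10, again the same when adjusted over the list alone (mean 0.68, adjusted p = 3.22e-08; adjusted p = 0.182 with an estimated correlation). Cyclin D3, which drives entry into the cycle (CD417852.1_492), was at least 8.83-fold higher (adjusted p = 3.48e-12), and the mitotic kinase CDKB (CX701149.1_775) at least 8.35-fold higher (adjusted p = 7.05e-12). Such bounds are given where a probe was not well above background on any array of the dimmer tissue in that comparison. They set the brighter tissue's mean against, on each array, the higher of the probe's own dim signal and the lowest signal among probes well above background. The ubiquitin-conjugating enzyme UBC20 (GMFL01-05-E20-R_384) was higher by 3.92 ± 0.14 and was well above background on 2 of 12 cortex channels.

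Ribosomal proteins were higher in phellogen for 192 of 204 probes, lower for 2 and not past the test for 10 (193, 2 and 9 adjusted over the list alone), with a mean of 1.05 (adjusted p = 1.25e-28; adjusted p = 0.217 with an estimated correlation). Examples were 60S ribosomal protein L39 (GMFL01-14-F24-R_344, 2.19 ± 0.10) and 40S ribosomal protein S12 (GMFL01-49-J11-R_206, 2.18 ± 0.08). A probe for 40S ribosomal protein S7 (GMFL01-27-B06-R_395) went the other way at -0.27 ± 0.09, a call that turned to 0.13 with median centring and was lost without phellogen replicate 3 (adjusted p = 0.0739) or 6 (adjusted p = 0.0595). Heat shock proteins were higher for 29 of 47 probes, lower for 10 and not past the test for 8, the same adjusted over the list alone (mean 0.35, adjusted p = 0.00936; adjusted p = 0.364 with an estimated correlation). With 1 probe per description this shift was lost (adjusted p = 0.112), and with median centring the mean was 0.54. The mitochondrial chaperonin Cpn60 (GMFL01-14-J03-R_635, 1.78 ± 0.09, well above background on 2 of 12 cortex channels) rose, and the small heat shock protein hsp22 (GMFL01-25-G04-R_360, -1.71 ± 0.16) fell.

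Wall and membrane genes of the phellogen included strong rises in lists that did not shift as wholes. The xyloglucan-remodelling enzyme XTH16 (CX710239.1_752) was higher by 3.26 ± 0.11, while expansins and XTHs as a list had 10 of 22 probes higher and 6 lower (adjusted p = 0.268). In pectin modification, 19 of 34 probes were higher and 9 lower (adjusted p = 0.0693). A pectate lyase-like protein (BM307685.1_337) was at least 7.27-fold higher and a polygalacturonase (GMFL01-23-M08-R_362), which cuts pectin chains, was higher by 2.79 ± 0.11. The cellulose synthase CesA2 (BI968823.1_464) rose by 2.75 ± 0.09, with 2 of 12 cortex channels well above background, but 11 of 19 probes of the cellulose, fasciclin and COBRA list were lower and 5 higher (adjusted p = 0.121, and 0.0489 with median centring, where the mean was -0.0033). The water channel PIP1;2 (GMFL01-44-M09-R_317) rose by 3.58 ± 0.09 (well above background on 4 of 12 cortex channels), and the aquaporin list went both ways, with 8 of 21 higher and 10 lower (adjusted p = 0.620, mean positive and test negative). Lipid transfer proteins had 4 of 7 higher and 2 lower (adjusted p = 0.315). A hybrid proline-rich protein, HyPRP (CD413045.1_536), rose by 3.78 ± 0.16. Beta-amyrin synthase AMS1 (GMFL01-26-E16-R_471), which cyclises oxidosqualene to a triterpene, was at least 3.53-fold higher (adjusted p = 9.68e-11). It was among 3 measured triterpene cyclase probes of 11 on the array, too few for a list test.

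Photosynthesis genes were lower in phellogen for 64 of 69 probes and higher for 0, with 5 not past the test, the same adjusted over the list alone (mean -1.18, adjusted p = 1.23e-15; adjusted p = 0.306 with an estimated correlation). The chlorophyll a/b-binding protein cab3 (GMFL01-08-F07-R_641) was at -3.66 ± 0.23, rubisco activase (GMFL01-29-K23-R_536) at -3.59 ± 0.13 and the rubisco small subunit (GMFL01-25-F02-R_286) at -3.27 ± 0.21. Phenylpropanoid and lignin genes were lower for 29 of 34 probes and higher for 4, with 1 not past the test, the same adjusted over the list alone (mean -1.23, adjusted p = 3.94e-06; adjusted p = 0.326 with an estimated correlation). Phenylalanine ammonia-lyase, the entry enzyme of the pathway (GMFL01-17-A15-R_584), was at -3.49 ± 0.25, 4-coumarate:CoA ligase 4CL1 (GMFL01-07-I17-R_145) at -3.39 ± 0.27 and cinnamate 4-hydroxylase (CF805860.1_584) at -3.23 ± 0.37. Isoflavonoid genes were lower for 24 of 31 and higher for 4, the same adjusted over the list alone, among them isoflavone synthase IFS1 (GMFL01-17-B03-R_484, -2.24 ± 0.16). Their mean was -0.64 (adjusted p = 2.86e-04; adjusted p = 0.217 with an estimated correlation), and -0.42 with 18 lower and 6 higher with median centring.

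Asparagine synthetase AS1 (GMFL01-13-P05-R_651) was lower by 27.2-fold, at -4.77 ± 0.24, AS2 (GMFL01-14-F20-R_547) was at -4.35 ± 0.26 and a further probe (GMFL01-15-F24-R_255) at -3.76 ± 0.22. AS1 and the further probe were well above background on 5 of 6 phellogen channels. Also among the largest falls were peptide methionine sulfoxide reductase (GMFL01-51-M23-R_265, -4.64 ± 0.12), a proline-rich protein precursor (GMFL01-10-I02-R_324, -4.38 ± 0.30), type 1 metallothionein (GMFL01-41-H18-R_362, -4.31 ± 0.15), SRC1 (GMFL01-30-H24-R_486, -3.97 ± 0.14), the sucrose-splitting enzyme invertase (CX702804.1_605, -3.81 ± 0.22) and an abscisic stress ripening-like protein (GMFL01-05-E04-R_337, -3.71 ± 0.09). Abscisic acid and late embryogenesis genes were lower for 5 of 10 probes and higher for 1, the same adjusted over the list alone (mean -0.80, adjusted p = 0.0189; adjusted p = 0.182 with an estimated correlation). This shift was lost on slide 2 alone (adjusted p = 0.0513) and with 1 probe per description (adjusted p = 0.0704). Its largest falls were in dehydrins, proteins of water deficit (GMFL01-42-O02-R_143, -2.52 ± 0.09, and AI966082.1_109, -2.22 ± 0.07). Proteases and nucleases were lower for 14 of 23 and higher for 5 (14 and 6 adjusted over the list alone, but 11 and 8 with median centring), with vacuolar processing enzyme VPE2 (GMFL01-19-O02-R_307) at -3.61 ± 0.16. The shift of that list (mean -0.46, adjusted p = 0.0461; adjusted p = 0.182 with an estimated correlation) was lost without phellogen replicate 4 (adjusted p = 0.0546), on slide 2 alone (adjusted p = 0.0513) and in 6 other settings.

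The following lists did not pass the test in phellogen. Ethylene genes had 1 of 10 higher and 2 lower, and 1 and 0 with median centring (adjusted p = 0.670, mean positive and test negative), with an ACC synthase probe (GMFL01-23-J10-R_259), for the step that commits to ethylene, at 1.41 ± 0.05 and the receptor ETR1 (CX710482.1_733) at -0.32 ± 0.06, a call lost with median centring (adjusted p = 0.483). Meristem regulators had 7 of 20 higher and 11 lower (adjusted p = 0.456), with LOB domain protein 12 (BU549572.1_431) at 1.06 ± 0.06 and the peptide gene CLE41 (CD415760.1_427) at 0.72 ± 0.08. Those probes were well above background on 7 and 9 of 12 cortex channels. Auxin genes had 3 of 17 higher and 8 lower, but 6 and 7 with median centring (adjusted p = 0.268). Hypoxia and fermentation genes had 7 of 21 higher and 9 lower, but 10 and 6 with median centring (adjusted p = 0.667), with sucrose synthase SS (GMFL01-18-F22-R_305) at 0.61 ± 0.10 (1.15 ± 0.14 with median centring) and sucrose synthase 2 (GMFL01-37-O11-R_263) at -1.06 ± 0.10. Peroxidases had 8 of 31 higher and 13 lower, but 10 each way with median centring (adjusted p = 0.674, mean positive and test negative), and PC7 (AW350350.1_648) was at -2.48 ± 0.12. Defence proteins had 11 of 31 higher and 17 lower (adjusted p = 0.226). Storage proteins with lipoxygenases had 3 of 23 higher and 13 lower, and sugar transport and cleavage genes 2 of 16 higher and 8 lower, each at adjusted p = 0.0518. Both lists lay at the threshold, and each passed as lower in 16 of 31 other settings, 6 of them with 1 array left out. These settings do not hold the estimated correlation, with which neither passed (adjusted p = 0.487 for storage proteins with lipoxygenases and 0.306 for sugar genes). Over the 31 settings the adjusted p ran from 0.0116 to 0.350 for storage proteins with lipoxygenases (0.0351 without phellogen replicate 3, 0.0430 without phellogen replicate 6) and from 0.0164 to 0.180 for sugar genes (0.0445 without phellogen replicate 1, 0.0412 without phellogen replicate 6). The other 4 such arrays, AP replicates 1, 3, 4 and 6, were the same for both lists and gave 0.0368 to 0.0497.

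Loess centres ratios at each intensity. With median centring in its place, the ratios of all probes moved by a median of 0.135 in phellogen, -0.0784 in AP and -0.207 in AP over phellogen, and the share of calls that were higher moved from 51.4% to 65.6%, from 45.1% to 22.3% and from 46.7% to 20.1%. Relative to that shift the lists described as shifted kept their direction, except where stated. Because arrays carry no measure of total RNA per cell, a ratio shows unequal change among transcripts and not absolute change.

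**Figure D1:**
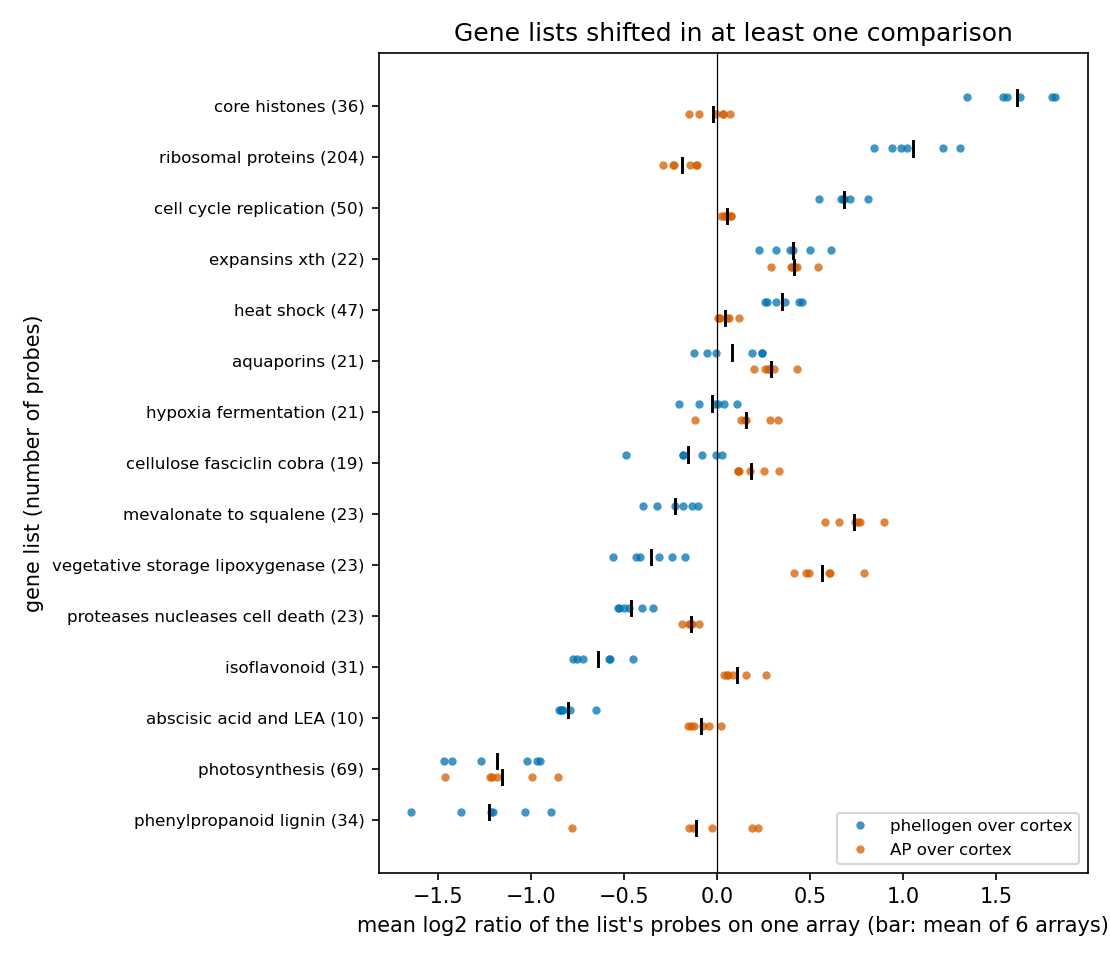
Mean log2 ratio over cortex of the probes of each fixed gene list that shifted in at least 1 comparison, 1 dot per array (6 phellogen, 6 AP) with a bar at the mean of 6 arrays. Core histones had a mean of 1.61 in phellogen and -0.02 in AP, and photosynthesis genes -1.18 and -1.15.

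The comparison of AP with cortex asked which transcripts mark the spongy tissue itself. AP had higher levels of genes from mevalonate to squalene, of storage proteins and lipoxygenases and of several single enzymes, and lower levels of photosynthesis genes. Here too the list shifts were lost with an estimated correlation. The largest rises were in a sulfotransferase (CX547767.1_786, 4.01 ± 0.26, 16.1-fold), an O-methyltransferase (BI971175.1_628, 3.93 ± 0.21), diamine oxidase, which breaks down polyamines (GMFL01-38-J10-R_347, 3.91 ± 0.30), and a 14-kDa proline-rich protein (CA850987.1_620, 3.90 ± 0.19). The largest falls were in cab3 (-3.91 ± 0.23, 15.1-fold lower) and asparagine synthetase AS1 (-3.47 ± 0.24). Of the 15981 probes, 5380 passed the test (33.7%), 2425 higher and 2955 lower, with 4147 of the same sign on all 6 arrays. By at least 2-fold, 189 were higher and 233 lower, 422 in all, against 710 with an offset of 16 and 2416 on the scanner's log ratio.

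The mevalonate pathway, which supplies squalene for sterols and triterpenes, was higher in AP for 19 of 23 probes and lower for 0, with 4 not past the test (20, 0 and 3 adjusted over the list alone). Its mean was 0.73 (adjusted p = 1.11e-12; adjusted p = 0.132 with an estimated correlation). Mevalonate kinase (GMFL01-32-M18-R_354) rose by 1.88 ± 0.12, isopentenyl pyrophosphate isomerase (GMFL01-52-J12-R_364) by 1.73 ± 0.09, HMG-CoA synthase (GMFL01-16-M07-R_203) by 1.58 ± 0.13 and a probe described by 3-hydroxy-3-methylglutaryl coenzyme A (CX707500.1_815) by 1.21 ± 0.18. In phellogen this list had 4 of 23 probes higher and 11 lower, but 5 each way with median centring (adjusted p = 0.226). Cycloartenol synthase, the first sterol cyclase (BM731211.1_467), was higher in AP by 2.21 ± 0.20. A second cycloartenol synthase probe (CO984997.1_611) was at 0.23 ± 0.05. Its call was lost with median centring (0.041, adjusted p = 0.797) and on slide 2 alone (0.18, adjusted p = 0.334). Without the dye term the call was lost while the value stayed at 0.23 (adjusted p = 0.0697). The beta-amyrin synthase AMS1 was not well above background on any AP array or cortex channel, so no fold is given. Cytochrome P450 CYP93E1, which hydroxylates beta-amyrin on the way to soyasaponins (GMFL01-52-D03-R_512), was higher in AP by 3.08 ± 0.15, against 1.33 ± 0.15 in phellogen.

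Vegetative storage proteins and lipoxygenases were higher in AP for 15 of 23 probes and lower for 2, the same adjusted over the list alone (mean 0.56, adjusted p = 2.03e-06; adjusted p = 0.191 with an estimated correlation). The lipoxygenases lox7 (GMFL01-10-E03-R_618) and vlxC (GMFL01-46-C11-R_407), which oxygenate fatty acids, were at 1.89 ± 0.16 and 1.82 ± 0.12. With no filter on dim probes this shift was lost (adjusted p = 0.0541). Expansins and XTHs were higher for 8 of 22 and lower for 2 (9 and 3 adjusted over the list alone), with XTH16 at 2.55 ± 0.11 and expansin dd263 (GMFL01-40-I02-R_485) at 1.83 ± 0.13. Their shift (mean 0.41, adjusted p = 0.0105; adjusted p = 0.321 with an estimated correlation) was lost on the scanner's own log ratio (adjusted p = 0.0562). Aquaporins were higher for 7 of 21 and lower for 2, the same adjusted over the list alone, but 4 each way with a mean of 0.15 with median centring (mean 0.29, adjusted p = 0.0217; adjusted p = 0.284 with an estimated correlation). An aquaporin (GMFL01-19-H19-R_483, well above background on 9 of 12 cortex channels) was at 2.01 ± 0.05 and PIP1;2 at 1.17 ± 0.09. That shift was lost on the scanner's log ratio (adjusted p = 0.0709) and with 1 probe per description (adjusted p = 0.206).

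Hypoxia and fermentation genes were higher in AP for 11 of 21 probes and lower for 4, the same adjusted over the list alone, but 4 higher and 5 lower with median centring, where the mean turned from 0.15 to -0.07. The adjusted p of 0.0399 (adjusted p = 0.446 with an estimated correlation) was lost in 16 settings. In some the mean changed little: without AP replicate 1 (0.145, adjusted p = 0.0592) or 5 (0.135, adjusted p = 0.0706), and without phellogen replicate 3 (0.154 as before, adjusted p = 0.0512). With 1 probe per description it turned to -0.040 (adjusted p = 0.621). Sucrose synthase SS was at 1.24 ± 0.10 and sucrose synthase 2 at -1.85 ± 0.10. On AP replicate 6 the list's mean was -0.12, against 0.13 to 0.33 on the other AP arrays.

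Other rises in AP were an anthocyanin 5-aromatic acyltransferase (GMFL01-28-O20-R_417, 2.89 ± 0.08), early nodulin N-75 (BG155375.1_289, 2.85 ± 0.20), alpha-isopropylmalate synthase of leucine synthesis (BE822724.1_262, 2.83 ± 0.15) and ornithine decarboxylase of polyamine synthesis (AW349137.1_709, 2.68 ± 0.14, well above background on 9 of 12 cortex channels). The lipid transfer-like protein AW100855.1_414 was at 2.59 ± 0.16. Pathogenesis-related PR1a (BI425441.1_54) was at 2.47 ± 0.36 and Sali3-2 (GMFL01-17-L05-R_562) at 2.45 ± 0.23, while the defence list had 12 of 31 higher and 7 lower, but 8 each way with median centring (adjusted p = 0.230). A cyclin-dependent kinase inhibitor 1;2 (CD396199.1_245), of a family that restrains the cell cycle, was at 0.72 ± 0.09. Cell cycle genes had 6 of 50 higher, 1 lower and 43 not past the test (5, 0 and 45 adjusted over the list alone; list adjusted p = 0.230, but 0.0107 with median centring, where 5 were higher and 1 lower). Core histones had 2 of 36 higher and 3 lower, and 1 and 5 with median centring (list adjusted p = 0.985). Members of both lists could pass the filter on phellogen signal alone. CDKB was well above background on 0 of 6 AP and 1 of 12 cortex channels, and cyclin D3 on 4 and 1. The 3 named histone H3 probes were so on 3 or 4 of 6 AP and 6 to 8 of 12 cortex channels. Where both signals are dim the offset draws them together, so these counts do not show equal levels in AP and cortex. In ethylene genes, 4 of 10 were higher and 1 lower, and 2 and 1 with median centring (adjusted p = 0.222), with ETR1 at 0.49 ± 0.06 (0.29 ± 0.08 with median centring) and an ACC synthase (GMFL01-05-P02-R_493) at 0.74 ± 0.13.

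Photosynthesis genes were lower in AP for 64 of 69 probes and higher for 0 (65 and 0 adjusted over the list alone), with a mean of -1.15 (adjusted p = 2.05e-31; adjusted p = 0.191 with an estimated correlation). Besides cab3, the photosystem II 10 kDa polypeptide (GMFL01-43-I06-R_366) was at -3.35 ± 0.12, the rubisco small subunit at -3.24 ± 0.21, rubisco activase at -3.05 ± 0.13 and plastocyanin (GMFL01-18-A20-R_317) at -2.81 ± 0.18. Small subunit and plastocyanin were well above background on 5 of 6 AP channels. Ribosomal proteins were lower for 76 of 204 and higher for 1 (77 and 1 adjusted over the list alone), by a small mean of -0.19 (adjusted p = 1.01e-06; adjusted p = 0.643 with an estimated correlation; mean -0.35 and 114 lower with median centring), with S7 at -1.09 ± 0.09 and L39 at -0.55 ± 0.10. The hydroxyproline-rich protein (-2.97 ± 0.18), methionine sulfoxide reductase (-3.10 ± 0.12), metallothionein (-2.91 ± 0.15) and invertase (-1.88 ± 0.22) were lower in AP as in phellogen. Phenylpropanoid genes had 5 of 34 higher and 5 lower, and 2 and 5 with median centring (adjusted p = 0.953), and phenylalanine ammonia-lyase at -0.16 ± 0.25 did not pass the test (adjusted p = 0.691). On AP replicate 6 the mean of that list was -0.78, against -0.15 to 0.22 on the other AP arrays. Peroxidases had 7 of 31 each way (adjusted p = 0.445, but 0.00340 on slide 2 alone), with a mean of -0.48 on AP replicate 6 against 0.11 to 0.42 on the others. Without AP replicate 6, 5006 probes passed the test. In the AP channels the arrays with the fewest probes well above background were replicate 5 (7552), replicate 1 (8062) and replicate 3 (10136). These arrays had AP in Cy3. With AP in Cy5, replicates 2, 4 and 6 had 11868, 12642 and 13427.

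**Figure D2:**
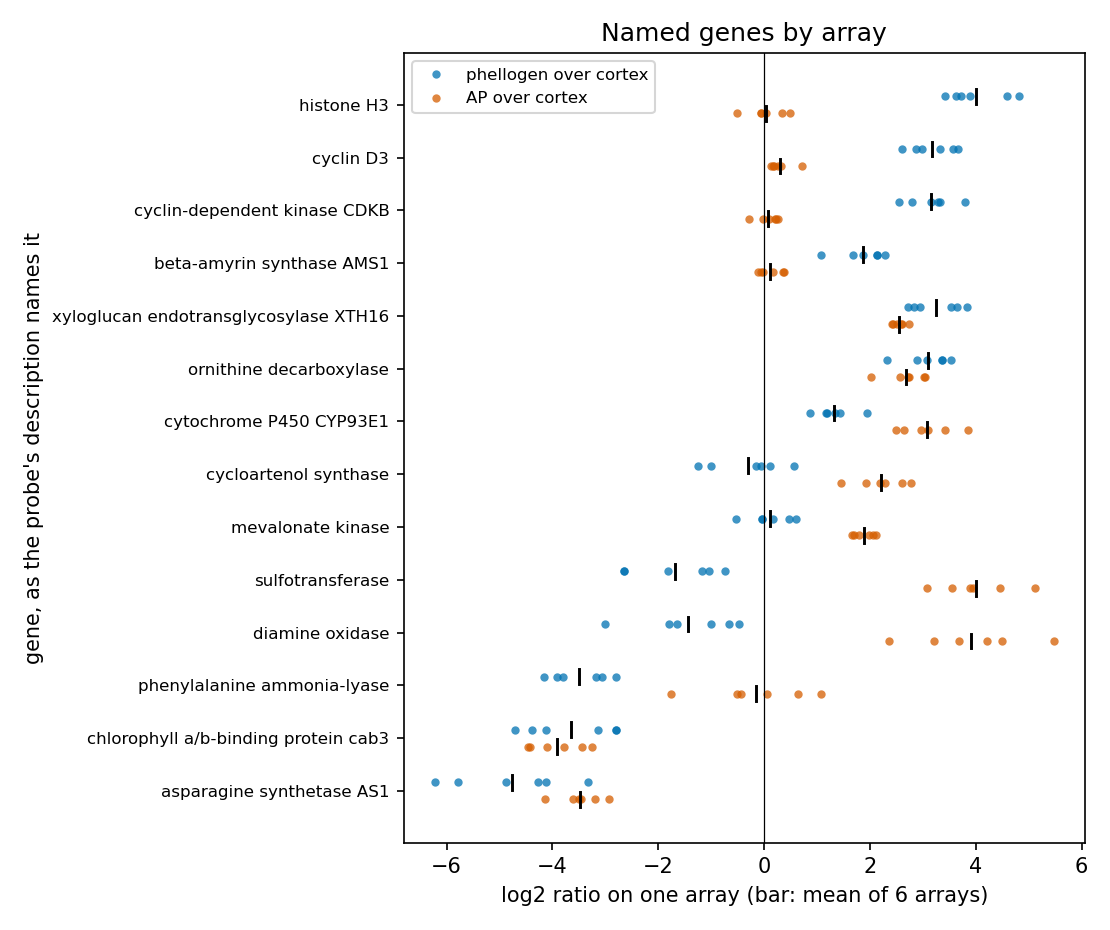
Log2 ratio over cortex of 14 named probes, 1 dot per array (6 phellogen, 6 AP) with a bar at the mean of 6 arrays. Histone H3, cyclin D3 and CDKB lay high in phellogen (the AP dots of cyclin D3 and CDKB rest on dim signal, with 1 of 12 cortex channels well above background for each and 0 of 6 AP channels for CDKB), and diamine oxidase was at -1.43 in phellogen and 3.91 in AP. The AP dots of beta-amyrin synthase AMS1 rest on dim signal too, with 0 of 6 AP and 0 of 12 cortex channels well above background.

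AP was set against phellogen through the cortex channel, which assumes that the cortex RNA of both sets of arrays is alike. AP had lower levels of histones, cell cycle genes and ribosomal proteins than phellogen, and higher levels of phenylpropanoid and isoflavonoid genes, of genes from mevalonate to squalene and of the list of storage proteins and lipoxygenases. As lists, these were no longer past the test with an estimated correlation. The largest rises were in PR1a (5.95 ± 0.51, 61.9-fold), the sulfotransferase (5.68 ± 0.36, 51.4-fold) and diamine oxidase (5.34 ± 0.42). The largest falls were in PvPRP1 (-4.13 ± 0.28, 17.5-fold lower) and histone H3 (GMFL01-25-K12-R_336, -4.06 ± 0.23). Of the 15981 probes, 8836 passed the test (55.3%), 4130 higher and 4706 lower in AP, of which 697 and 870 by at least 2-fold, 1567 in all (2516 with an offset of 16 and 5837 on the scanner's log ratio). Slide 2 alone held both kinds of array. With slide as a block 4537 probes passed, 4450 of them among the 8836, and on the 4 arrays of slide 2 alone 3579 passed, 3511 of them among the 8836. The block left the size of the contrast about the same (slope of 1.00 over the 8836 probes, 1549 called and changed at least 2-fold), while its SE grew by a median factor of 1.78.

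The contrast estimate is the same with slide as a block as on slide 2 alone, and it is given after each list's mean as the slide 2 mean. All 11 shifted lists passed in both of these fits, with adjusted p of at most 0.0254 and 0.0370. Core histones were lower in AP than in phellogen for 30 of 36 probes and higher for 2, the same adjusted over the list alone (mean -1.63, slide 2 mean -1.63, adjusted p = 1.37e-13; adjusted p = 0.137 with an estimated correlation). The further probes CX706384.1_491 and BE821002.1_520 for histone H3 were at -3.97 ± 0.21 and -3.98 ± 0.16, the probe for histones H3 and H4 at -3.43 ± 0.15 and UBC20 at -3.77 ± 0.19. In AP these probes and PvPRP1 were well above background on 3 or 4 of 6 arrays. Cell cycle genes were lower for 36 of 50 and higher for 5, the same adjusted over the list alone (mean -0.63, slide 2 mean -0.57, adjusted p = 4.54e-07; adjusted p = 0.137 with an estimated correlation). CDKB was at least 7.89-fold lower and cyclin D3, well above background on 4 of 6 AP channels, was at -2.87 ± 0.13. Ribosomal proteins were lower for 192 of 204 and higher for 1 (194 and 1 adjusted over the list alone; mean -1.24, slide 2 mean -1.29, adjusted p = 6.16e-39; adjusted p = 0.137 with an estimated correlation), with L39 at -2.74 ± 0.15 and S12 at -2.25 ± 0.11. Heat shock genes were lower for 24 of 47 and higher for 9 (26 and 9 adjusted over the list alone; mean -0.31, slide 2 mean -0.32, adjusted p = 0.00923; adjusted p = 0.303 with an estimated correlation). Cpn60 was at least 3.37-fold lower, and hsp22 was higher by 2.78 ± 0.23. The heat shock shift was lost with 1 probe per description (adjusted p = 0.0836), and with median centring 27 were lower and 3 higher (mean -0.60).

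Phenylpropanoid genes were higher in AP than in phellogen for 27 of 34 probes and lower for 3, the same adjusted over the list alone (mean 1.11, slide 2 mean 1.15, adjusted p = 6.02e-06; adjusted p = 0.269 with an estimated correlation). Cinnamate 4-hydroxylase was at 4.09 ± 0.53, phenylalanine ammonia-lyase at 3.33 ± 0.36 and 4CL1 at 2.99 ± 0.38, each called lower in phellogen than in cortex and not past the test between AP and cortex. AP replicate 6 had the lowest mean of this list among AP arrays (-0.78 against cortex). Isoflavonoid genes were higher for 22 of 31 and lower for 4, the same adjusted over the list alone (mean 0.75, slide 2 mean 0.67, adjusted p = 2.99e-05; adjusted p = 0.137 with an estimated correlation), with IFS1 at 3.19 ± 0.22. With median centring 12 isoflavonoid probes were higher and 4 lower, and the mean was 0.36. Genes from mevalonate to squalene were higher for 15 of 23 and lower for 2 (16 and 3 adjusted over the list alone; mean 0.96, slide 2 mean 1.08, adjusted p = 8.06e-06; adjusted p = 0.153 with an estimated correlation). Isopentenyl pyrophosphate isomerase was at 2.49 ± 0.13, HMG-CoA synthase at 2.64 ± 0.19, mevalonate kinase at 1.78 ± 0.16 and cycloartenol synthase BM731211.1_467 at 2.51 ± 0.28. The beta-amyrin synthase AMS1, in contrast, was at least 3.27-fold lower in AP (adjusted p = 1.91e-08).

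Storage proteins and lipoxygenases were higher for 15 of 23 and lower for 3, the same adjusted over the list alone (mean 0.92, slide 2 mean 1.02, adjusted p = 1.89e-04; adjusted p = 0.168 with an estimated correlation), with lox7 at 2.92 ± 0.22 and vlxC at 2.13 ± 0.17. Abscisic acid and late embryogenesis genes were higher for 5 of 10 and lower for 0, the same adjusted over the list alone (mean 0.71, slide 2 mean 0.69, adjusted p = 0.0131; adjusted p = 0.137 with an estimated correlation). With median centring the mean was 0.39, with 4 higher and 1 lower. The dehydrins GMFL01-42-O02-R_143 and AI966082.1_109 were at 2.56 ± 0.13 and 2.25 ± 0.10 (1.57 ± 0.21 and 1.503 ± 0.22 with median centring). Cellulose, fasciclin and COBRA genes were higher for 13 of 19 and lower for 1, the same adjusted over the list alone (mean 0.34, slide 2 mean 0.32, adjusted p = 0.00438; adjusted p = 0.263 with an estimated correlation), the lower one being CesA2 at -2.74 ± 0.12 (well above background on 2 of 6 AP channels). With median centring 7 of that list were higher and 1 lower, and the mean was 0.082. Proteases and nucleases were higher for 12 of 23 and lower for 3, the same adjusted over the list alone, but 8 each way with a mean of 0.068 with median centring (mean 0.32, slide 2 mean 0.32, adjusted p = 0.0265; adjusted p = 0.137 with an estimated correlation), with VPE2 at 2.00 ± 0.23. With no filter on dim probes, the shifts of these 4 lists and of the heat shock list were lost (adjusted p = 0.0706 for each). With 1 probe per description, the abscisic acid (adjusted p = 0.0587) and protease (adjusted p = 0.394) shifts were lost.

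Photosynthesis genes, far below cortex in both tissues, had 8 of 69 higher and 4 lower in AP than in phellogen (adjusted p = 0.474, mean 0.03, slide 2 mean -0.20), and on slide 2 alone the list passed as lower (adjusted p = 0.0184). The balance turned to 1 higher and 16 lower with median centring (mean -0.25) and to 4 higher and 9 lower with scaling between arrays (mean -0.15). Rubisco activase was at 0.54 ± 0.18, a call lost with slide as a block (0.33 ± 0.32, adjusted p = 0.488) and turned to -0.13 ± 0.19 with median centring. Single genes with large rises in AP over phellogen were Sali3-2 (5.10 ± 0.33), a cytochrome P450 described by the CYP4, CYP19 and CYP26 subfamilies (GMFL01-18-D19-R_403, 5.01 ± 0.24), trypsin inhibitor p20 (CF920954.1_716, 4.72 ± 0.47), the O-methyltransferase (4.25 ± 0.30), the probe described by 3-hydroxy-3-methylglutaryl coenzyme A (3.94 ± 0.25) and peroxidase PC7 (3.51 ± 0.17). Trypsin inhibitor p20 was well above background on 4 of 6 phellogen channels. The pectate lyase-like protein was at least 6.90-fold lower in AP. Defence proteins had 17 of 31 higher and 12 lower (mean 0.59, adjusted p = 0.117). They passed as higher with median centring (12 each way, mean 0.29, adjusted p = 0.0124) and on slide 2 alone (mean 0.65, adjusted p = 0.0349). Sugar transport and cleavage genes had 7 of 16 higher and 2 lower (9 and 3 adjusted over the list alone). Their adjusted p was 0.0888, or 0.269 with an estimated correlation. They passed in 5 of 31 other settings, among them median centring (adjusted p = 0.0153) and slide 2 alone (adjusted p = 0.0370). Pectin modification genes had 6 of 34 higher and 15 lower (adjusted p = 0.0932). Ethylene genes had 2 of 10 higher and 1 lower, but 1 and 2 with median centring (adjusted p = 0.415), with ETR1 at 0.82 ± 0.09 and ACC synthase GMFL01-23-J10-R_259 at -1.26 ± 0.07 (0.36 ± 0.12 and -1.90 ± 0.16 with median centring, both still past the test). ACC synthase GMFL01-05-P02-R_493 was at 0.82 ± 0.18, and its call was lost with slide as a block (0.49 ± 0.31, adjusted p = 0.254) and with median centring (0.47 ± 0.22, adjusted p = 0.0831). For cycloartenol synthase CO984997.1_611 (0.29 ± 0.07) the block left the value at 0.29 and widened its SE to 0.13 (adjusted p = 0.130), while median centring turned it to -0.16 ± 0.14.

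Both tissues shared part of their difference from cortex. XTH16, ornithine decarboxylase (3.09 ± 0.14 in phellogen) and the anthocyanin acyltransferase (2.91 ± 0.08 in phellogen) were higher in both, and photosynthesis genes, asparagine synthetases and metallothionein were lower in both. Of probes called in both comparisons, 1161 were higher in both and 1936 lower in both, against 878 and 1011 for independent lists. In opposite directions, 552 were higher in phellogen and lower in AP and 665 the reverse, against 1070 and 829. All 1217 were called between AP and phellogen, which follows from 2 opposite calls that share 1 SE. Across probes the ratios correlated at 0.363 with a covariance of 0.0897. With no effect but cortex noise shared by same-numbered arrays, 100 simulations gave a mean correlation of 0.50 and a covariance of 0.00338. Whether such arrays shared cortex RNA is not known. The remaining 0.0863 also holds expression particular to cortex, the denominator of both ratios, so it is not an effect of phellogen and AP alone. With phellogen from odd and AP from even replicates the correlation was 0.429 and 2241 probes moved alike, and the reverse split gave 0.317 and 1726. Each such part held 1 dye orientation, opposite in the 2 tissues, so the dye effect of the fit over all 12 arrays was subtracted beforehand, and a dye effect that differs between tissues would stay in these values. With both dyes in each part and a dye term, phellogen replicates 1 to 3 against AP 4 to 6 gave 0.351 and 1295, and the reverse 0.319 and 1954. Of probes higher in phellogen and not called in AP against cortex (4072), 3209 were called lower in AP than in phellogen, and of those lower in phellogen and not called in AP (2865), 1983 were called higher in AP.

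**Figure D3:**
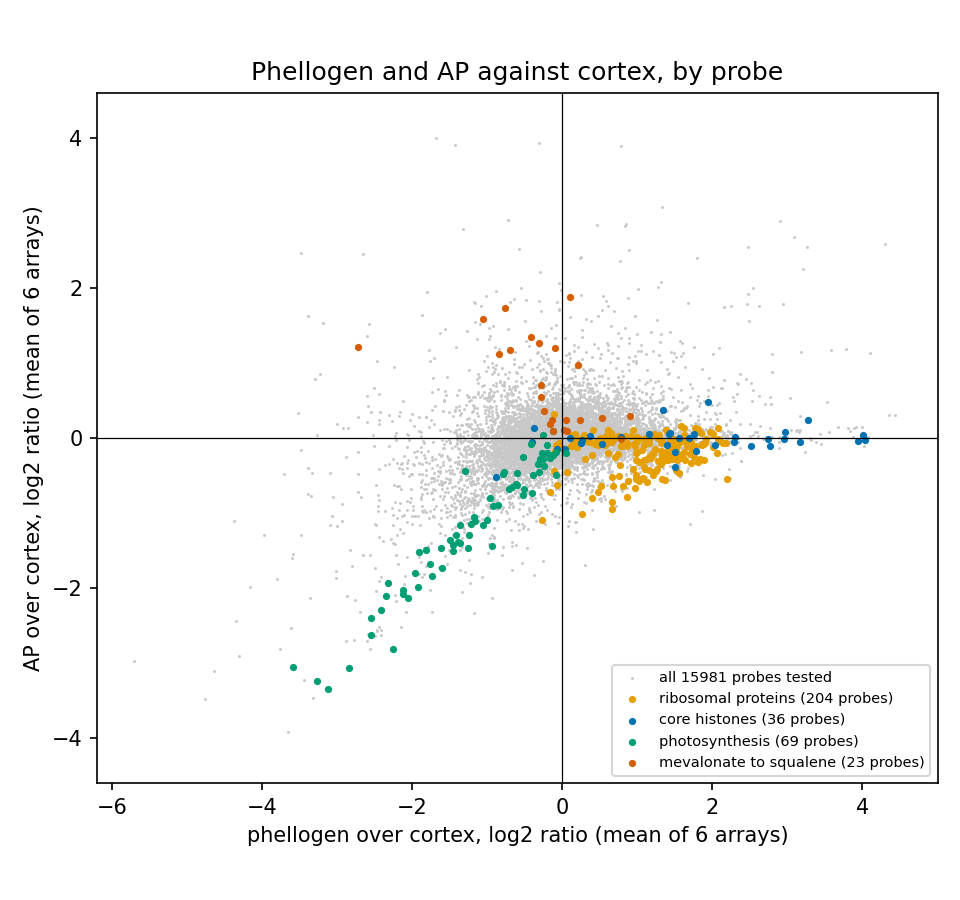
Log2 ratio over cortex in phellogen (horizontal) and AP (vertical), each the mean of 6 arrays, for 15981 probes, with 4 gene lists coloured. Ribosomal proteins and core histones spread along the phellogen axis, photosynthesis genes lay low in both tissues, and probes from mevalonate to squalene lay high in AP (mean 0.73).

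Among lists meant as markers of other cell types, vascular markers had 8 of 16 higher and 4 lower in phellogen (adjusted p = 0.580) and 3 higher and 1 lower in AP, but 1 and 2 with median centring (adjusted p = 0.207). Most probes that this list took were protein phosphatases, so it says little of vascular tissue. In AP against phellogen it had 4 higher and 2 lower, but 2 and 8 with median centring (adjusted p = 0.705). Epidermal markers (3 of 6 on the array), suberin, cutin and wax genes (3 of 34) and cytokinin and gibberellin genes (2 of 20) had too few measured probes to test.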

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

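The tests of cortex RNA in the AP captures and of a phellogen array under an AP label were chosen only after the results had been seen. The 77 described probes and the 24 tested fixed lists were searched for single arrays far from the other 5 of their set and for opposite differences in the 2 tissues, and no other probes were searched. Of 202 sets of 6 values, 12 had an extreme array beyond Dixon's critical value (5.94%), where chance gives about 1 in 20. Of these 9 were in AP, 7 of them at AP replicate 6, and 3 were in phellogen.

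On AP replicate 6 the log2 ratio over cortex was -4.01 for asparagine synthetase AS2 (others -2.54 to -1.79), -3.30 for invertase (others -1.72 to -1.43), -2.49 for VPE2 (others -1.69 to -1.25), 0.26 for the cyclin-dependent kinase inhibitor 1;2 (others 0.70 to 0.88) and 0.04 for hsp22 (others 1.15 to 1.48). On the same array the phenylpropanoid list had a mean of -0.78 (others -0.15 to 0.22) and the peroxidase list -0.48 (others 0.11 to 0.42). Cyclin D3 was at 0.71 on AP replicate 3 (others 0.13 to 0.32), but it was well above background on 1 of 12 cortex and 4 of 6 AP channels, so these ratios rest on dim signal. The ratio of lox7 was 2.91 on AP replicate 1 (others 1.39 to 1.89). In phellogen, isopentenyl pyrophosphate isomerase was at -1.19 on replicate 2 (others -0.79 to -0.58), the P450 described by CYP4, CYP19 and CYP26 at -2.31 on replicate 3 (others -3.79 to -3.36), and the abscisic acid list at -0.65 on replicate 6 (others -0.85 to -0.79).

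AP replicate 6 stood apart from the other AP arrays, with correlations across probes of 0.533 to 0.731 with them against 0.719 to 0.888 among them, and of 0.398 to 0.460 with phellogen arrays against 0.0955 to 0.436 for the other AP arrays, so its highest correlation with phellogen exceeded theirs. Phellogen RNA in that capture would raise histones there, but the core histone mean was -0.152 on that array, below -0.0962 to 0.0707 on the others and far from 1.61 in phellogen. That argues against phellogen RNA but rests on 1 list, so phellogen RNA is not excluded. Over all probes the array's deviation from the other AP arrays had a slope of 0.177 toward phellogen. The mean of the other AP arrays enters both sides of that slope, which alone pushes it up. A phellogen array under an AP label is excluded, since the highest correlation of AP replicate 6 with a phellogen array was 0.460 and the lowest between phellogen arrays was 0.849. Another mix of cells in the capture or a plant that responded otherwise may still lie behind it, and neither was tested.

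Changes against cortex were smaller in AP than in phellogen, with 5380 against 11251 probes called and spreads of the ratios of 0.366 and 0.674. Cortex RNA in the AP captures would shrink the fall of photosynthesis genes in AP alike, yet across 69 probes the slope of AP on phellogen ratios was 0.953 (95% interval over probes 0.890 to 1.03, which leaves out the variation between arrays), above the 0.544 that the spreads would need. With the arrays of each set drawn again 100 times it ran from 0.757 to 1.11, and with single AP arrays on the phellogen mean from 0.794 to 1.11, each time above the slope needed there (at most 0.621 and 0.666). The level of cab3 in AP was 6.64% of that in cortex. Dimmer AP signal does not account for the whole gap, since among 6417 probes well above background in all channels 77.9% were called in phellogen and 48.4% in AP, a ratio of 1.61 (95% interval over probes 1.57 to 1.66). That ratio was 2.09 over all probes, so part of the gap may come with dim signal. Tissue, which the design names, stays open and was not tested.

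Several genes were called higher than cortex in 1 tissue and lower in the other in limma. Their called difference between AP and phellogen follows from these opposite calls. AP minus phellogen was 5.95 for PR1a, 5.68 for the sulfotransferase, 5.34 for diamine oxidase, 5.10 for Sali3-2, 5.01 for the P450 described by CYP4, CYP19 and CYP26, 4.72 for trypsin inhibitor p20 and 3.51 for peroxidase PC7, all higher than cortex in AP and lower in phellogen. In isoprenoid synthesis it was 3.94 for the probe described by 3-hydroxy-3-methylglutaryl coenzyme A, 2.64 for HMG-CoA synthase and 2.49 for isopentenyl pyrophosphate isomerase. It was 3.19 for IFS1, 2.92 for lox7, 2.13 for vlxC, 2.78 for hsp22 and 0.82 for ETR1, in the same direction. With median centring the phellogen side was lost for ETR1 (-0.07, adjusted p = 0.483) and vlxC (-0.031, adjusted p = 0.881). The reverse held for 60S ribosomal protein L39 at -2.74 and for the ribosomal protein list, whose mean difference was -1.24. That list's mean in AP was small at -0.19, with 127 of 204 probes not past the test. With an estimated correlation it passed in no comparison.

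The contrast of AP with phellogen runs through cortex RNA, which may have differed between the sets of arrays. Over the 8836 called probes, the difference in cortex signal carried a share of 0.083 of the contrast (0.0532 to 0.116 when arrays were left out in turn), against the share of at least 0.5 that this explanation needs. The SD of the difference was 0.793 in the tissue channels and 0.162 in the cortex channels. Tissue, which the design names, stays open as the explanation, and slide remains partly entangled with it. With slide as a block 4537 probes passed, but 1549 of these changed at least 2-fold against 1567 without the block. Over the 8836 probes the contrast had a slope of 1.00 on its value without the block and kept its sign for 8773, and its SE grew by a median factor of 1.78. Among the 4386 probes whose call was lost, the median size of the contrast was 0.32 without the block and 0.28 with it.

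In all 3 counts the real grouping of arrays gave the most calls. Its share of the groupings tried, 0.031 for phellogen, 0.031 for AP and 0.01 for AP against phellogen, is the smallest this test can give. Chance was therefore made unlikely but not excluded. Groupings with 1 array turned or moved gave the highest other counts. Of the 32 sign patterns of 6 arrays, only the real 1 gave as many calls for phellogen (11251, highest other 7033) and only the real 1 for AP (5380, highest other 787). Of 100 drawn from 462 splits of the 12 arrays into sets of 6, only the real 1 gave as many calls between AP and phellogen (8836, highest other 5162).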

How the results depend on the processing

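Tests with the slide as a fixed block, slide 2 alone, replicates 1 to 3 against 4 to 6, the 8 added lists and 1 probe per description were chosen only after the data had been seen. The naming rule took 140 pairs of a comparison with 1 of the 77 described probes. Over 4200 values of these pairs across settings, 4170 kept direction and call, 27 were no longer past the threshold and 3 reversed. The 77 probes were picked with their values in view, so part of this stability may come from the selection. Among all genes that the naming rule took, 79 calls were lost on slide 2 alone, which has fewer arrays. For these genes 27 calls between AP and phellogen were lost with slide as a fixed block. Median centring ended 28 of their calls, apart from 8 that reversed. Of all 198 called values of the described probes, median centring kept 184, ended the call of 9 and turned 5, none of these then past the test. Among the probes called in phellogen, AP and AP over phellogen, 8 of 69, 6 of 58 and 21 of 71 described ones moved by over 1.5 times with median centring. There, 8 genes that the naming rule took reversed, none of them then past the test: GMFL01-27-B06-R_395 (0.13) and CX709458.1_602 (0.038) in phellogen, BI968141.1_697 (-0.082) in AP, and CO984997.1_611 (-0.16), GMFL01-04-O11-R_392 (-0.060), GMFL01-29-K23-R_536 (-0.13), GMFL01-14-B02-R_234 (-0.15) and CX707156.1_743 (-0.24) in AP over phellogen. The cause was not tested. With slide as a fixed block 4537 probes passed between AP and phellogen. The 4 arrays of slide 2 alone gave 6208, 2123 and 3579 for phellogen, AP and AP over phellogen and an overlap of 1108, with fewer arrays by construction. The overlap of 3097 became 1726 with phellogen from even and AP from odd replicates (1 dye orientation per part, with the dye effect of all 12 arrays subtracted), 1295 with phellogen replicates 1 to 3 and AP 4 to 6, and 1954 with the reverse. List shifts in AP fell from 7 to 4 on the scanner's log ratio, 4 on the series' value table and 4 at the threshold of 0.01, and in AP over phellogen from 11 to 6 with no filter. They rose to 12, 9 and 13 with median centring, and on slide 2 alone went from 9 to 7 in phellogen, 7 to 9 in AP and 11 to 14 in AP over phellogen. With an estimated correlation 0, 0 and 0 fixed lists passed, and the added lists gave 5, 3 and 2 shifts. Leaving out each array gave 10568 to 11312 probes for phellogen, 4430 to 5515 for AP, 8232 to 8930 for AP over phellogen, an overlap of 2606 to 3123, and 8 to 11, 6 to 8 and 11 to 12 list shifts. In 0 of 6 pairs did arrays with the same replicate number deviate together (r from -0.552 to -0.0239). The median was -0.152 for other pairs with the same dye orientation. Same-numbered arrays share that orientation, and a dye effect that differs between tissues would push their r down. Whether the numbers pair arrays is therefore undecided. A replicate block gave 10801, 4757 and 8226 probes, and no array correlated best with its own number. As a random block, slide had a correlation of 0.00572. Probes changed by at least 2-fold numbered 1735, 422 and 1567 with the offset of 50 and 2789, 710 and 2516 where the offset alone was set to 16. They numbered 6191, 2367 and 5665 on the scanner's processed signals with loess and 6238, 2416 and 5837 on the scanner's ratios, which differ in background correction as well. The share of probes well above background was lowest where AP was in Cy3 (17.7% to 23.7%), and 26767 dim probes were left out.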

Other observations

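The 8 lists described here were chosen only after the probe descriptions had been read, before any ratio was looked at. Tubulins and kinesins, the fibres and motors of the cytoskeleton, were higher than cortex in phellogen for 39 of 56 probes and lower for 6 (mean 0.54, adjusted p = 1.03e-05; adjusted p = 0.147 with an estimated correlation). In AP they were higher for 28 and lower for 1 (mean 0.34, adjusted p = 3.44e-11; adjusted p = 0.0685 with an estimated correlation), and 21 and 1 with median centring. A beta-tubulin (BI969940.1_709) was at 2.07 ± 0.11 in AP and -0.05 ± 0.11 in phellogen, where it did not pass the test (limma adjusted p = 0.695), with a difference of 2.12 ± 0.16. Between AP and phellogen the list had 9 probes higher and 21 lower (mean -0.20, adjusted p = 0.125). With median centring it had 3 higher and 30 lower (mean -0.49, adjusted p = 0.135). Glycolysis genes were higher for 38 of 66 and lower for 10 in phellogen (mean 0.29, or 0.47 with 43 higher and 7 lower with median centring; adjusted p = 0.00164; adjusted p = 0.147 with an estimated correlation). In AP 18 were higher and 4 lower (mean 0.15, adjusted p = 2.86e-05, or 0.0685 with an estimated correlation). With median centring 5 were higher and 4 lower, the mean was 0.03 and the adjusted p was 0.00216. Between AP and phellogen 8 were higher and 27 lower (mean -0.14, adjusted p = 0.0714). With median centring 3 were higher and 34 lower (mean -0.44, adjusted p = 0.115).

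Ethylene response factors, transcription factors downstream of the hormone, were lower than cortex in phellogen for 14 of 27 probes and higher for 2 (mean -0.37, adjusted p = 0.00352; adjusted p = 0.147 with an estimated correlation). With median centring 8 were lower and 7 higher, the mean was -0.12 and the shift was lost (adjusted p = 0.0530). In AP over phellogen 19 were higher and 3 lower (mean 0.46, slide 2 mean 0.45, adjusted p = 1.42e-04, or 0.0365 with an estimated correlation). It was the 1 list tested to pass with an estimated correlation, but it was adjusted over the 6 added lists alone. Before adjustment its camera p with an estimated correlation was 0.00608. The mevalonate list in AP against cortex had 0.00549 and did not pass among the 24 fixed lists. With median centring, however, 0 ethylene response factors were higher in AP than in phellogen and 4 lower, with a mean of 0.02. The direction of single members therefore rests on the loess step, although relative to the other probes the list still passed (adjusted p = 0.0351). ERF5 (CX548434.1_718) was at 0.99 ± 0.18 in that contrast, a call lost with slide as a block, where the value stayed at 0.87 ± 0.34 and its SE grew (adjusted p = 0.0730), and with median centring, where it fell to 0.19 ± 0.20 (adjusted p = 0.446). Against cortex, AP had 9 higher and 6 lower, but 4 and 6 with median centring (adjusted p = 0.174).

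Cytochrome P450 genes were lower in phellogen than in cortex for 30 of 45 probes and higher for 11 (mean -0.52, adjusted p = 0.00193; adjusted p = 0.147 with an estimated correlation). In AP over phellogen 25 were higher and 7 lower (mean 0.57, slide 2 mean 0.57, adjusted p = 2.43e-04; adjusted p = 0.108 with an estimated correlation), and 21 and 7 with a mean of 0.33 with median centring. AP against cortex had 11 higher and 10 lower, but 8 and 11 with median centring (adjusted p = 0.531). A wider photosynthesis list had 85 of 91 probes lower and 0 higher in phellogen (adjusted p = 2.62e-18; adjusted p = 0.147 with an estimated correlation) and the same counts in AP (adjusted p = 4.11e-37; adjusted p = 0.0685 with an estimated correlation). It holds the probes of the fixed photosynthesis list. A wider wax and cutin list of 7 probes did not shift in phellogen (adjusted p = 0.133), AP (adjusted p = 0.552) or their difference (adjusted p = 0.0714). Wider oxidosqualene cyclases (3 of 14 on the array) and amended vascular markers (1 of 14) had too few measured probes to test.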
